A study of Homo sapiens with 12 samples.

How the data were processed

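Transcript levels were measured with Affymetrix HG-U133 Plus 2.0 arrays, hybridised with biotin-labelled RNA of cultured primary human decidual cells from pregnancies at term. The series held 12 arrays in 4 groups of 3: estradiol alone, estradiol plus medroxyprogesterone acetate (MPA, a synthetic progestin), and each of these with interleukin-1β (IL-1β, a cytokine of the innate immune response). Per the labels' protocols, confluent cells received 1e-08 M estradiol with or without 1e-07 M MPA for 7 days, followed by 24 h in serum-free medium and then 1 ng/ml IL-1β, or none, for 6 h. One protocol text places a rinse that removed the steroids before IL-1β was added, while the design text names steroid and cytokine together for the last 6 h, so whether steroid was present during those hours is open. Array groups and letters (A, B and C in every group) came from the titles. The labels do not say whether the 3 arrays of a group came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical.

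The authors deposited 1 table of log2 values, 1 column per array and 54675 probe sets. The software that summarised and scaled the arrays is not given in the sources used here. The values show how the table was scaled: for 28043 probe sets (51.3%) the median over the 12 arrays was 1 on the linear scale, within 0.001, while it was below 1 for 26629 and above 1 for 3. The table thus holds values relative to a median and no measured brightness, so levels of different genes cannot be compared with each other. What a median below 1 marks is not stated, so no probe set could be called absent. The other probe sets near 0 given for NR4A3, SLC39A14, LINC01088, MYB, IRAK2 and NEFM were not among those with median 1. CILP, named for MPA, stood below 0 on every array. A floor ratio of 0.01 (log2 -6.64) held 31 values of 9 probe sets, 18 of them in the estradiol group, 13 in the estradiol plus MPA group and 0 in the groups with IL-1β. The fold change of a gene whose tested probe set has a floored value (CXCL1, CXCL3, CXCL8, IL6 and CCL20) is therefore a lower bound, written as "at least". Arrays at the floor show no spread, as for CCL20 and CXCL3 on every array without IL-1β. The errors and p-values of these genes can thus be too small. Array medians over all probe sets ran from -0.3539 to -0.2463 and those over the probe sets with median 1 from -0.0239 to 0.0230. The 3' minus 5' difference of the ACTB control probe sets ran from 0.038 to 0.086 under estradiol and from -0.181 to -0.056 with MPA. With IL-1β these groups overlapped, and the GAPDH difference overlapped between the MPA groups throughout. Whether RNA quality bears on the MPA effects was not tested. The mean of the hybridisation spike probe sets ran from 0.358 to 0.464 in A and from -0.381 to -0.026 in B. In C it ran from -0.114 to -0.050, except for estradiol plus MPA C at 0.590. A thus stood apart from B, while B and C overlapped. Whether the letters mark steps of processing was not tested. The log2 values were used as deposited. The number of arrays limits the precision, and the median standard error of a simple comparison was 0.173 on the log2 scale (0.132 with a term for the letter).

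Probe sets were named through the platform annotation, with symbols checked by Entrez ID against the RefSeq gene table. Of the probe sets, 41091 had 1 gene symbol, 1801 several and 11721 none, and 62 were controls. 41037 matched a RefSeq gene and 0 received a newer symbol. XIST, TSIX and Y-linked genes (77 probe sets) were left out of every step. The remaining 41014 probe sets represented 19732 genes, 10505 of which had several. Each gene was represented by the probe set with the highest mean over all 12 arrays, a choice made without the group labels. On a table of values relative to a median this does not select the brightest probe set. The mean there depends on the change itself, so the choice is not neutral to the size of an effect. Most other probe sets of median 1 stood higher than the value used among the raised genes named for IL-1β under estradiol. Examples were ICAM1 (7.39 and 7.55 against 5.67) and IRAK2 (4.50 against 1.91). Those of SLC39A14, PLAUR and PTGES stood lower. 12702 genes had at least 1 probe set with median 1.

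A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and Benjamini-Hochberg adjustment was made over the 19732 genes within each comparison, with an adjusted p of 0.05 as the threshold. The comparisons were the IL-1β effect under estradiol, the IL-1β effect under estradiol plus MPA, the MPA effect without and with IL-1β, the interaction (the difference between the 2 IL-1β effects), and the average effect of each factor. Errors given after ± are standard errors of the fit unless SD is written. Exact two-sided permutation tests were run for PGR, and with 3 arrays against 3 their p cannot go below 0.1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the table and drew the figures.

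Whether the letters pair the arrays was read from the data, since the labels do not say what they mark. Deviations from the group means correlated between arrays of the same letter at 0.416 to 0.786 in all 18 pairs, against -0.629 to 0.173 between letters, and all 12 arrays matched best an array of their own letter. The letters thus appear to pair the arrays, which the fit above, with no letter term, ignores. Counts and calls come from that fit, fixed beforehand, unless they are called blocked. The fit with the letter as a block was planned as an alternative to the fit without it, and its value stands beside a result where it changes a call or moves a count by more than 1.5 times; these values are called blocked.

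The groups, the tests, the alternatives, the rule for named genes and 28 gene lists (550 genes, 509 of them measured) were fixed before the data were examined. The lists covered inflammation (chemokines; cytokines and haematopoietic growth factors; NF-kB subunits and feedback inhibitors; the IL-1 and Toll-like receptor pathway; leukocyte adhesion and antigen presentation; interferon-stimulated genes; immediate early genes), the decidua and its hormones (steroid receptors and cofactors, decidualization markers, progestin and glucocorticoid responsive genes, oestrogen responsive genes, uterine activation and contraction, prostaglandin synthesis, transport and receptors), matrix and vessels (matrix metalloproteinases and inhibitors, collagens and other matrix proteins, haemostasis and fibrinolysis, angiogenic factors) and cell state (oxidative stress and metallothioneins, unfolded protein response, cell cycle, cholesterol synthesis, housekeeping genes). Others held markers of leukocytes, trophoblast, endothelium, epithelium, smooth muscle and pericytes, and stroma. Each list was tested with camera at its preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. Genes named in the text were PGR in every comparison, the 10 higher and 10 lower genes of largest change among those past the threshold whose groups of arrays did not overlap, and at most 5 members of each list past the threshold or, where none passed, at most 2 as values. Where fewer than 5 genes passed, the 5 of smallest p were eligible. Genes named from the blocked fit followed the same rule with every same-letter pair moving one way in place of groups that did not overlap, and this extension was chosen after seeing the data.

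The steps were tested on simulated data made from the fitted spread of the 19732 genes with 200 genes changed. In the IL-1β effect under estradiol 49% of genes changed by a log2 of 1 and 79% of those changed by 2 were recovered (66% and 98% with the block), with 1 false call (12 with the block). In the MPA effect without IL-1β these shares were 49% and 78% (69% and 91% with the block) with 2 false calls (6), and in the interaction 29% and 64% (38% and 83%) with 2 (8). The average MPA effect had 0 false calls (17 with the block). The alternatives tried were quantile normalization, 2 ways of centring the arrays, the mean of a gene's probe sets, every probe set on its own, leaving out the genes of lowest mean, a trended robust variance, array weights, only the arrays of the groups compared, a 2-fold minimum and leaving out each array in turn.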

Results

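Expression was measured on 12 arrays of human decidual cells, the transformed stromal cells of the lining of the pregnant uterus, with 3 arrays (A, B and C) in each of 4 groups. The cells had been kept in estradiol or in estradiol plus MPA, and each of these cultures was studied without and with IL-1β. The title of the series names inhibition of the progesterone receptor gene PGR by IL-1β and preterm birth with chorioamnionitis as its subject, so PGR is described first. The deposited values were log2 values relative to a median, without brightness, and 19732 genes were tested. Arrays are named by group and letter, with n = 3 in every group.

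PGR encodes the nuclear receptor through which progesterone acts, and 2 probe sets represent it. The probe set that represented the gene in the tests, here called the first, averaged 1.49 ± 1.26 (SD) under estradiol, -0.24 ± 0.91 with IL-1β, 0.03 ± 1.40 with MPA and -1.27 ± 0.40 with both. With IL-1β this mean stood 3.31-fold lower under estradiol (log2 fold change -1.72 ± 0.81) and 2.46-fold lower under estradiol plus MPA (-1.30 ± 0.81). Neither difference passed the test (limma adjusted p = 0.553 and 0.876, and 0.0601 and 0.187 blocked). On this probe set the value was lower with IL-1β in every same-letter pair of both comparisons. With 1 array left out the differences lay between -2.42 and -1.19 and between -1.96 and -0.57. The second probe set had tighter groups, with means of 2.01 ± 0.80 (SD) under estradiol, 0.08 ± 0.54 with IL-1β, -0.21 ± 0.39 with MPA and -2.01 ± 0.46 with both. Its IL-1β difference was 3.81-fold under estradiol (-1.93 ± 0.44) and 3.48-fold under estradiol plus MPA (-1.80 ± 0.44). Over all probe sets these did not pass without the letter (adjusted p = 0.0777 and 0.141; 0.0228 for the first without estradiol C), but passed in the blocked fit (0.00117 and 0.00203, and without any 1 array). In exact two-sided permutation tests the second probe set reached the smallest possible p of 0.1 in both comparisons, and the first gave 0.3 in both. These tests shuffle the arrays without regard to the letters, so spread between letters enters them.

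The PGR means stood lower with MPA as well. On the first probe set the difference was 2.75-fold without IL-1β (-1.46 ± 0.81) and 2.04-fold with it (-1.03 ± 0.81). Neither passed (adjusted p = 0.990 and 1, and 0.331 and 0.562 blocked), although the value was lower with MPA in every same-letter pair. On the second the differences were 4.67-fold (-2.22 ± 0.44) and 4.26-fold (-2.09 ± 0.44), which passed only in the blocked fit (adjusted p = 0.0231 and 0.0315, against 0.528 and 0.779 without the letter). The blocked call without IL-1β was lost on leaving out estradiol A (0.126), estradiol B (0.157), estradiol plus MPA A (0.108) or estradiol plus MPA B (0.117). The blocked call with IL-1β was lost on leaving out any 1 of its 6 arrays (0.109 to 0.246). Averaged over MPA, the IL-1β effect on the second probe set was -1.86 and passed in both fits (adjusted p = 0.0102, and 0.000134 blocked), also without any 1 array. On the first this average was -1.51 and passed only in the blocked fit (0.0170, against 0.245). Averaged over IL-1β, the MPA effect on the second probe set was -2.16 and passed only in the blocked fit (0.00317, against 0.108), there without any 1 array as well (0.00595 to 0.0246). Without the letter it passed only on leaving out estradiol C (0.0449). On the first it was -1.24 and passed in neither fit (0.80, and 0.122 blocked). The response of PGR to IL-1β did not differ detectably with MPA, with an interaction of 0.43 ± 1.15 on the first probe set and 0.13 ± 0.62 on the second, each with an adjusted p of 1.

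**Figure D1:**
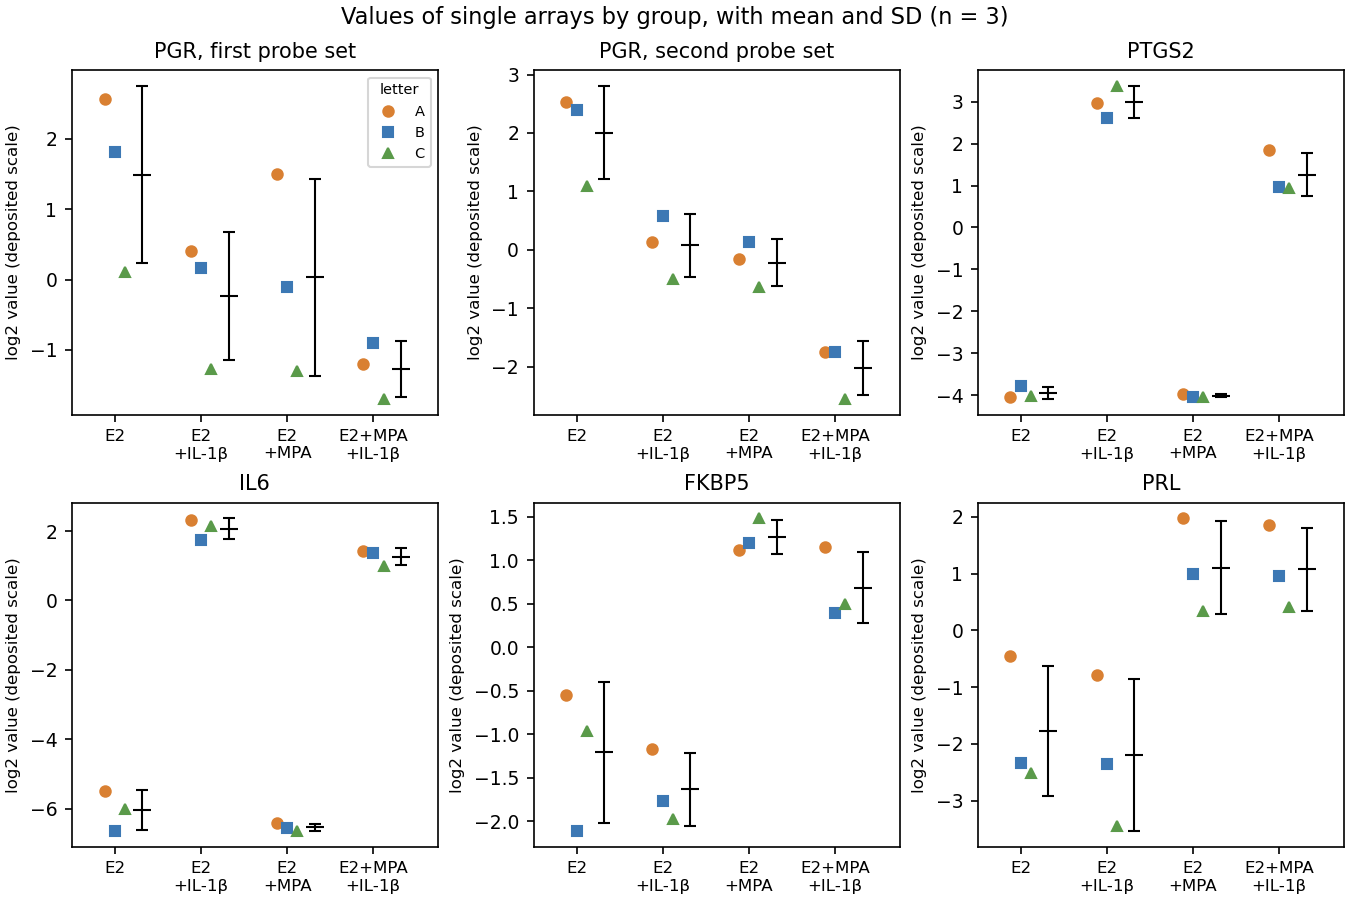
Deposited log2 values of both PGR probe sets, PTGS2, IL6, FKBP5 and PRL on every array, by group, with the letters A, B and C as separate symbols and the mean and SD (n = 3) beside them. PTGS2 averaged -3.95 under estradiol and 2.99 with IL-1β, with no overlap of the arrays, whereas the arrays of the first PGR probe set spread widely within groups (SD 1.26 under estradiol).

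IL-1β under estradiol raised genes of inflammation most. CXCL6, a chemokine for neutrophils, rose 348-fold (log2 fold change 8.44 ± 0.39), and IL6, a cytokine that drives the acute-phase response, rose at least 277-fold, from -6.04 ± 0.58 (SD) to 2.07 ± 0.30. IL1B, which encodes the stimulating cytokine itself, rose 231-fold (7.85 ± 0.28). PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose 122-fold (6.93 ± 0.25), from -3.95 ± 0.14 (SD) to 2.99 ± 0.38 (SD). Among genes that fell, DKK1, a secreted Wnt antagonist, was lower 10.8-fold (-3.43 ± 0.52). ETV1, an ETS transcription factor, was lower 8.96-fold (-3.16 ± 0.43), while its 4 other probe sets stood between -1.38 and -0.01 and did not pass. LRIG3, a membrane protein of growth factor signalling, was lower 6.17-fold (-2.63 ± 0.32). In all, 299 of 19732 genes passed (limma, adjusted p under 0.05), 197 higher and 102 lower, and 931 passed in the blocked fit (490 higher, 441 lower), among them all 299.

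Of 20 chemokines, 10 rose and 10 did not pass (14 rose when adjusted over the list alone), with a median log2 fold change of 4.85. CXCL1 (at least 323-fold, 8.34 ± 0.31) and CXCL8 (at least 164-fold, 7.36 ± 0.35) attract neutrophils, CCL20 (at least 255-fold, 7.99 ± 0.19) attracts dendritic cells and lymphocytes, and CXCL10 (208-fold, 7.70 ± 0.55) attracts T cells. Among 21 cytokines and haematopoietic growth factors, 6 rose and 15 did not pass (15 rose adjusted over the list alone; 11 rose when blocked; median 1.78). These included CSF3, the granulocyte growth factor (137-fold, 7.10 ± 0.65), TSLP, a cytokine that acts on dendritic cells (62.7-fold, 5.97 ± 0.30), and LIF, a cytokine of implantation (34.8-fold, 5.12 ± 0.25). For NF-kB subunits and feedback inhibitors, 14 of 21 rose and 7 did not pass (18 adjusted over the list alone; median 2.59). TNFAIP3, a deubiquitinase that restrains NF-kB, rose 75.0-fold (6.23 ± 0.19), RIPK2, a kinase upstream of NF-kB, 11.4-fold (3.51 ± 0.20) and the subunit gene NFKB1 10.2-fold (3.36 ± 0.30). Against the other genes, camera gave adjusted p values of 1.39e-32, 3.11e-22 and 6.06e-41 for these 3 lists, and with an estimated correlation adjusted p = 0.00155, 0.000263 and 0.000134. BCL2A1, an NF-kB target that protects from apoptosis, rose 205-fold (7.68 ± 0.32).

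Leukocyte adhesion and antigen presentation held 8 genes of 20 that rose and 12 that did not pass (14 adjusted over the list alone; median 1.27). ICAM1 and VCAM1, the ligands of leukocyte integrins, rose 50.8-fold (5.67 ± 0.29) and 40-fold (5.32 ± 0.58). The checkpoint ligand CD274 rose 5.61-fold (2.49 ± 0.20) and the peptide transporter TAP1 4.71-fold (2.24 ± 0.24). Other probe sets stood higher and passed, at 7.39 and 7.55 for ICAM1 and 3.51 for CD274. The camera adjusted p of this list was 5.93e-20, and adjusted p = 0.000868 with an estimated correlation. Interferon-stimulated genes had a median of 1.40, but 2 of 28 rose and 26 did not pass (11 adjusted over the list alone), while 5 rose when blocked. The 2 were IRF1, a transcription factor that NF-kB also induces (5.53-fold, 2.47 ± 0.25), and the guanylate-binding protein GBP2 (3.17-fold, 1.67 ± 0.21). Their other probe sets stood at 3.36 and 3.18 and passed. The camera adjusted p of 2.06e-14 for this list became adjusted p = 0.166 with an estimated correlation. Immediate early genes, the first transcribed after a stimulus, counted 5 of 19 that rose and 14 that did not pass (7 adjusted over the list alone, and 12 higher and 1 lower when blocked; median 0.79; camera adjusted p = 1.64e-10, and adjusted p = 0.00630 with an estimated correlation). They included the nuclear receptor NR4A3 (18.6-fold, 4.22 ± 0.43; 4.88, past the threshold, and 0.06 on its other probe sets), the phosphatase DUSP5 (9.50-fold, 3.25 ± 0.40) and JUNB (3.55-fold, 1.83 ± 0.19). Oxidative stress genes and metallothioneins held 5 of 22 that rose and 17 that did not pass (7 higher and 1 lower adjusted over the list alone; median 0.55). Blocked, 9 of them rose, and 9 were higher and 3 lower over the list alone. SLC39A14, a zinc and iron importer, rose 11.9-fold (3.58 ± 0.41) and the metallothionein MT2A 1.78-fold (0.83 ± 0.13), with camera adjusted p = 0.000490 for the list, and adjusted p = 0.178 with an estimated correlation. Of the other probe sets of SLC39A14, 1 passed at 2.74 and 1 stood at -0.04.

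In the list of prostaglandin synthesis, transport and receptors, 2 of 21 rose and 19 did not pass (3 adjusted over the list alone; median 0.08; camera adjusted p = 0.0637). PTGES, the enzyme that makes prostaglandin E2 downstream of PTGS2, passed only in the blocked fit (9.61-fold, 3.26 ± 0.17, adjusted p = 8.45e-05, against 0.0664). Of 21 matrix metalloproteinases and inhibitors, 1 rose, 1 fell and 19 did not pass, with the same counts adjusted over the list alone (blocked 4 rose and 1 fell, and 4 and 2 over the list alone). MMP9, a gelatinase, rose 10.4-fold (3.38 ± 0.53), and ADAMTS1, a protease of proteoglycans, fell by 1.66 ± 0.31 (its other probe set stood at -0.68 and did not pass). The collagenase MMP1 (7.51-fold, 2.91 ± 0.30, adjusted p = 0.00240) and the elastase MMP12 (31-fold, 4.95 ± 0.75, adjusted p = 0.0123) passed only in the blocked fit, in which this list had camera adjusted p = 0.0173, against 0.0679 without the letter. With an estimated correlation the blocked call was lost (adjusted p = 0.282). Decidualization markers were mixed, with 2 of 29 higher, 1 lower and 26 not passing (4 and 2 adjusted over the list alone; blocked 4 higher and 2 lower over all genes; median 0.04; camera adjusted p = 0.207). STAT5A, a transcription factor of the prolactin pathway, rose 13.6-fold (3.76 ± 0.24) and DKK1 was the one that fell. FOXO1, a transcription factor of decidualization (-1.17 ± 0.16, adjusted p = 0.00880), and HSD11B1, which regenerates cortisol (4.60 ± 0.54, adjusted p = 0.00428), passed only in the blocked fit on the probe sets used. Of the other probe sets of FOXO1, 1 passed without the letter at -2.14 (0.0299) and 1 stood at 0.02. Of 29 progestin and glucocorticoid responsive genes, MT2A alone passed and 28 did not (5 rose adjusted over the list alone; median 0.02; camera adjusted p = 0.343), but when blocked 6 rose and 2 fell (6 and 3 over the list alone). Of 16 steroid receptors and cofactors 0 passed over all genes by limma or adjusted over the list alone, and when blocked 1 and 4 were lower (median -0.13; camera adjusted p = 0.131). The 22 cell cycle genes had a median of -0.29, with 0 past the threshold over all genes (2 lower when blocked), 2 lower adjusted over the list alone, camera adjusted p = 0.000187 and adjusted p = 0.215 with an estimated correlation.

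All 299 genes had groups of arrays that did not overlap, as did 2861 genes (14.5%) in this comparison, against the 10% that chance gives without regard to the letters. For IL-1β under estradiol plus MPA this share was 10.0%, and for MPA without and with IL-1β 7.24% and 5.50%. A chance share that respects the letters was not computed, so shares at or below 10% do not show that an effect is absent. The count fell to 166 without estradiol B, 176 without estradiol plus IL-1β C and 189 with only the groups compared, and the blocked count lay between 428 and 618 without any 1 of the 6 arrays. Calls were lost for DKK1 without estradiol A (adjusted p = 0.0555), for MMP9 without estradiol B, estradiol C, estradiol plus IL-1β A or C (up to 0.0679). ADAMTS1 was lost without estradiol B or estradiol plus IL-1β A, B or C (up to 0.119), and MT2A without estradiol A, estradiol B, or estradiol plus IL-1β B or C (up to 0.0703). With only the groups compared DKK1, MT2A and ADAMTS1 did not pass (0.10, 0.0780 and 0.185), and ADAMTS1 was also lost with quantile normalization (0.0756), a trended robust variance (0.126) and array weights (0.0549). The cell cycle list was lost without estradiol B (camera adjusted p = 0.0550), where its median was -0.08. Of 28 other probe sets of 18 genes named in this comparison without the block, 27 had the same sign and 12 lay within a log2 of 1 of the value used.

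**Figure D2:**
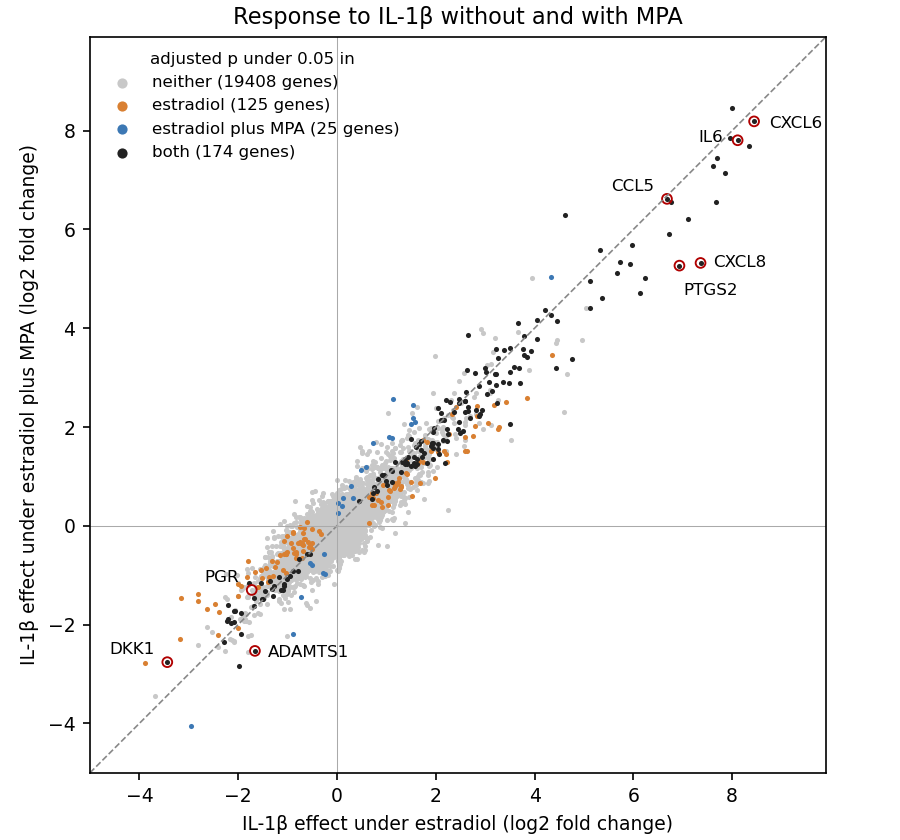
Log2 fold change of each of 19732 genes with IL-1β under estradiol (horizontal axis) and under estradiol plus MPA (vertical axis), coloured by where the gene passed an adjusted p of 0.05, with the line of equal effects dashed. Of the genes, 174 passed in both, 125 under estradiol only and 25 under estradiol plus MPA only, and these last counts are not a test of a difference.

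With MPA present, IL-1β again raised genes of inflammation most. CCL20 rose at least 354-fold (8.47 ± 0.19), CXCL6 291-fold (8.19 ± 0.39), IL6 at least 224-fold (7.80 ± 0.27), IL1B 140-fold (7.13 ± 0.28) and CCL5, a chemokine for T cells and monocytes, 98.3-fold (6.62 ± 0.37). PTGS2 rose 38.5-fold (5.27 ± 0.25), from -4.01 ± 0.04 (SD) to 1.25 ± 0.51. The genes that fell included ADAMTS1 (5.78-fold lower, -2.53 ± 0.31), GPR183, an oxysterol receptor that guides immune cells (4.57-fold lower, -2.19 ± 0.27), and PWWP3B (7.13-fold lower, -2.83 ± 0.35). Here 199 genes passed (limma, adjusted p under 0.05), 155 higher and 44 lower, and 562 in the blocked fit (351 higher, 211 lower), which kept 197 of the 199.

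Chemokines (10 of 20 rose, 10 did not pass; 15 adjusted over the list alone; median 4.16) and NF-kB genes (11 of 21 rose, 10 did not pass; 18 adjusted over the list alone; median 2.35) had camera adjusted p values of 2.36e-39 and 1.26e-42. In the cytokine list 7 of 21 rose and 14 did not pass (13 adjusted over the list alone; median 1.80; camera adjusted p = 2.78e-23), with CSF3 at 74.1-fold (6.21 ± 0.65) and LIF at 31.1-fold (4.96 ± 0.25). Adhesion and antigen presentation counted 8 of 20 that rose and 12 that did not pass (12 adjusted over the list alone; median 1.06; camera adjusted p = 2.11e-18), with VCAM1 48.2-fold higher (5.59 ± 0.58) and ICAM1 34.8-fold higher (5.12 ± 0.29). With an estimated correlation these 4 lists had adjusted p = 0.000875, 0.000115, 0.000221 and 0.000875. The other probe sets of ICAM1 stood at 6.08 and 6.36 and passed. TNFAIP3 rose 32.4-fold (5.02 ± 0.19), RIPK2 8.71-fold (3.12 ± 0.20), STAT5A 11.9-fold (3.57 ± 0.24) and NR4A3 20.5-fold (4.36 ± 0.43; 4.60, past the threshold, and 0.09 on its other probe sets). Of 19 immediate early genes 5 rose and 14 did not pass (6 adjusted over the list alone; median 0.73), with camera adjusted p = 1.30e-07, and adjusted p = 0.0180 with an estimated correlation (0.0764 blocked). Interferon-stimulated genes again had 2 of 28 that rose, IRF1 (5.57-fold, 2.48 ± 0.25) and GBP2 (3.14-fold, 1.65 ± 0.21), and 26 that did not pass (6 adjusted over the list alone; median 1.24). Their camera adjusted p was 1.35e-13, and adjusted p = 0.146 with an estimated correlation.

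Oxidative stress genes and metallothioneins had 1 of 22 that rose, SLC39A14 (9.31-fold, 3.22 ± 0.41; 2.34, past the threshold, and -0.02 on its other probe sets). The other 21 did not pass (5 higher and 1 lower adjusted over the list alone; median 0.24). Blocked, 5 rose, and 8 were higher and 1 lower over the list alone. Their camera adjusted p was 0.00801, and adjusted p = 0.30 with an estimated correlation. Prostaglandin genes again held 2 of 21 that rose and 19 that did not pass (3 adjusted over the list alone; median 0.05; camera adjusted p = 0.146), with PTGES passing only when blocked (5.83-fold, 2.54 ± 0.17, adjusted p = 0.000344, against 0.225). Metalloproteinases and inhibitors held MMP9, which rose 11.7-fold (3.55 ± 0.53), and ADAMTS1, which fell, with 19 of 21 not passing (2 higher and 1 lower adjusted over the list alone; median 0.11). With the block 5 rose and 1 fell, and 6 and 2 over the list alone. MMP1 passed only when blocked (15.9-fold, 3.99 ± 0.30, adjusted p = 0.000674), and so did the metalloproteinase list (camera adjusted p = 0.0326, against 0.146, but adjusted p = 0.356 with an estimated correlation in the same fit). Of 29 decidualization markers 1 rose, 1 fell and 27 did not pass (3 and 3 adjusted over the list alone; blocked 3 rose and 2 fell, and 7 and 3 over the list alone; median 0.17; camera adjusted p = 0.165). FOXO1 fell by 1.29 ± 0.16 only in the blocked fit (adjusted p = 0.00750, against 0.190; its other probe sets stood at -1.44 and -0.01 and did not pass without the letter). Among 29 progestin and glucocorticoid responsive genes TSC22D3, a glucocorticoid-induced leucine zipper, fell by 0.97 (adjusted p = 0.0263; its other probe sets stood at -1.49 and 0.00 and did not pass). The other 28 did not pass (2 higher and 4 lower adjusted over the list alone; blocked 1 rose and 3 fell, and 5 and 5 over the list alone; median -0.04; camera adjusted p = 0.951). SGK1, a kinase of the same list, fell by 1.38 ± 0.12 only when blocked (adjusted p = 0.00126, against 0.152).

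Fits with only the groups compared left 64 genes, and ended the calls of CSF3 (adjusted p = 0.0684), NFKB1 (0.0640; 2.92 ± 0.30 with all arrays), CD274 (0.0657; 1.88 ± 0.20), IRF1 (0.0753), GBP2 (0.0642), SLC39A14 (0.0717), PWWP3B (0.117), MMP9 (0.198) and TSC22D3 (0.266). The count was 128 without estradiol plus MPA B, 101 without estradiol plus MPA plus IL-1β A and 132 without estradiol plus MPA plus IL-1β C, and the blocked count fell to 228 to 351 without any 1 of the arrays other than estradiol plus MPA A. Without the same 3 arrays the call of MMP9 was lost (up to 0.0701), and that of TSC22D3 without estradiol plus MPA B or C or estradiol plus MPA plus IL-1β A or B (up to 0.107). TSC22D3 was also lost with quantile normalization (0.107) and a trended robust variance (0.114). The oxidative stress list was lost without estradiol plus MPA A (camera adjusted p = 0.0774), without estradiol plus MPA B (0.0882; median -0.04) and without estradiol plus MPA plus IL-1β C (0.223; median -0.03).

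Both IL-1β effects were close across genes, with a Pearson correlation of 0.898 and a Spearman correlation of 0.635 over 19732 genes, which are not independent replicates. They rest on different arrays. Of the 324 genes that passed in either, 138 were higher in both (1.55 expected of independent lists), 36 were lower in both (0.227 expected) and 0 passed in opposite directions by limma. Averaged over MPA, the effect of IL-1β passed for 759 genes (437 higher, 322 lower), and for 1920 in the blocked fit (866 higher, 1054 lower; 1231 without estradiol plus MPA plus IL-1β A).

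MPA alone, set against estradiol, gave no gene past the threshold (0 by limma in either fit, with 812 genes at an unadjusted p under 0.05 and 1935 when blocked). The smallest p values belonged to CILP, a matrix protein (log2 fold change 0.78 ± 0.09, adjusted p = 0.211), IMPA2, an inositol phosphatase (2.14 ± 0.28, 0.296), ATPAF1, an assembly factor of ATP synthase (-0.68 ± 0.10, 0.371; 0.19 on its second probe set), LINC01088, a noncoding RNA (2.47 ± 0.37, 0.383), and ARC, an immediate early gene (0.99 ± 0.16, 0.389). FKBP5, a co-chaperone of steroid receptors and a classic progestin and glucocorticoid target, stood 5.55-fold higher (2.47 ± 0.39, 0.389). PRL, the decidual hormone prolactin, stood 7.34-fold higher (2.88 ± 0.79, adjusted p = 0.990), and in the blocked fit its error shrank to 0.24 with an adjusted p of 0.0568. The same adjusted p was reached by GLUL, glutamine synthetase (1.30 ± 0.13), MMP1 (-2.81 ± 0.30), OLFML1 (-2.55 ± 0.27) and LRRC17 (-1.83 ± 0.19), each moving one way in 3 of 3 letters. These 5 passed when the block was joined with arrays centred on their medians, the mean of probe sets or a trended robust variance (0.0141 to 0.0411). With the mean of probe sets GLUL stood at 0.94 and LRRC17 at -0.98, whose other probe set stood at -0.13.

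As a group the 29 progestin and glucocorticoid responsive genes were higher with MPA, with a median of 0.39 and camera adjusted p = 2.47e-06. None passed over all genes and 29 did not, and 3 were higher adjusted over the list alone (10 when blocked). This was the only list of this comparison that held with an estimated correlation (adjusted p = 0.0443, and 0.0780 when blocked). Decidualization markers had a median of 0.20 (0 of 29 passed; 2 higher adjusted over the list alone, 9 when blocked), with camera adjusted p = 0.00816, and adjusted p = 0.252 with an estimated correlation. Cell cycle genes (median -0.26, camera adjusted p = 2.47e-06), interferon-stimulated genes (-0.29, 0.000499) and oestrogen responsive genes (-0.10, 0.00830) were lower as groups, with 0 members passing over all genes or adjusted over the list alone (blocked, 1 oestrogen responsive gene was higher and 3 lower over the list alone). With an estimated correlation these 3 had adjusted p = 0.252, 0.549 and 0.124. Markers of smooth muscle and pericytes moved with MPA too, with a median of 0.39 (0 of 15 passed; 0 adjusted over the list alone, 5 when blocked; camera adjusted p = 0.00849, and adjusted p = 0.532 with an estimated correlation). In the blocked fit metalloproteinases (camera adjusted p = 0.0314), oxidative stress genes (0.0161) and housekeeping genes (0.0343) also passed, against 0.197, 0.0677 and 0.0733. None of these 3 held with an estimated correlation in the same fit (adjusted p = 0.451, 0.363 and 0.291).

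Leaving out estradiol C gave 4 genes, estradiol plus MPA B 1 and estradiol plus MPA C 6, with CILP passing without either of the last (adjusted p = 0.0318 and 0.0375) and IMPA2 without estradiol plus MPA C (0.0282). CILP also passed with a trended robust variance (0.0391). When blocked, the same arrays left out gave 16, 1 and 17, with MMP1 passing in the first case (0.0425). The camera call was lost for interferon-stimulated genes without estradiol B (adjusted p = 0.112; median -0.15), and by letter their median was -0.01 in A, -0.94 in B and 0.14 in C. It was lost for oestrogen responsive genes without estradiol B (0.104; median -0.04) or estradiol plus MPA A (0.0565). It was also lost for smooth muscle markers without estradiol C (0.251; median 0.24), estradiol plus MPA A (0.0877; median 0.20) or B (0.129), and for decidualization markers without estradiol plus MPA C (0.130).

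**Figure D3:**
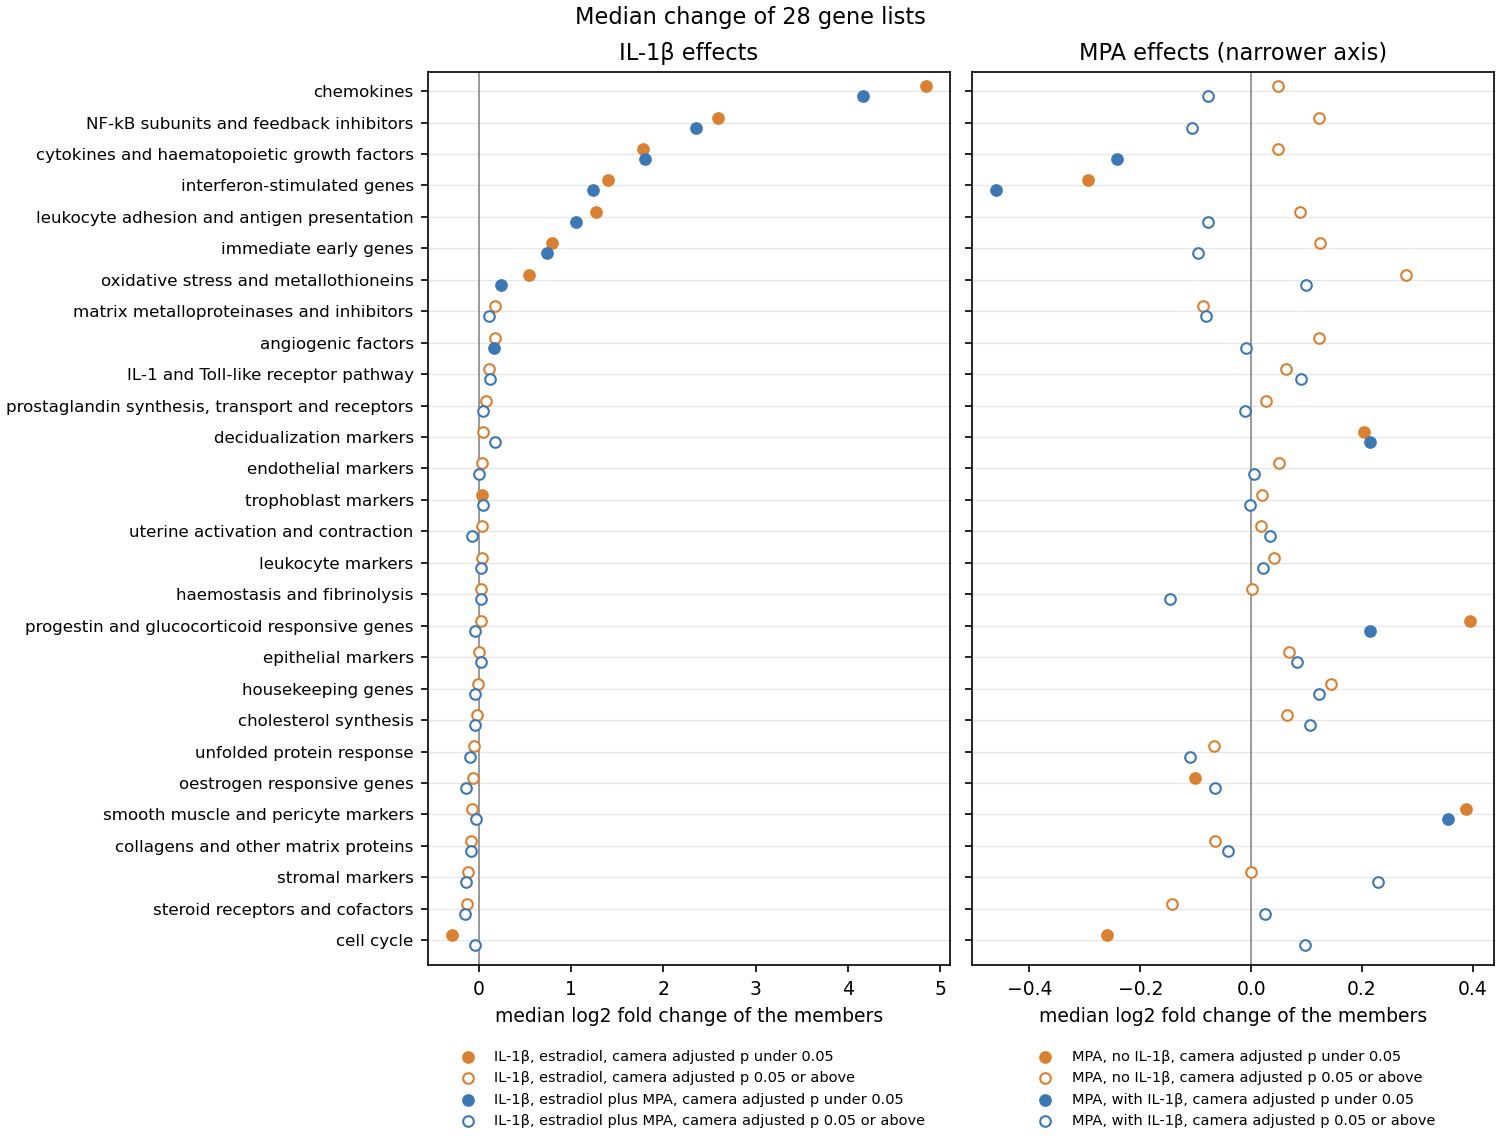
Median log2 fold change of the members of 28 gene lists with IL-1β (left, under estradiol and under estradiol plus MPA) and with MPA (right, without and with IL-1β, on a narrower axis), filled where the camera adjusted p was under 0.05. Chemokines had the highest medians with IL-1β, 4.85 and 4.16, and medians of 0.05 and -0.08 with MPA.

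With IL-1β present, MPA again gave 0 genes past the threshold by limma (616 at an unadjusted p under 0.05). SLC7A11, the cystine transporter of glutathione synthesis, stood 3.32-fold lower with MPA (-1.73 ± 0.20, adjusted p = 0.125), and IMPA2 5.20-fold higher (2.38 ± 0.28, 0.125). RRAD, a small GTPase (0.81 ± 0.11, 0.256), PTGS2 (-1.73 ± 0.25, 0.327), LINC01088 (2.38 ± 0.37, 0.359) and FKBP5 (2.32 ± 0.39, 0.489) followed. In the blocked fit 1 gene passed (1655 at an unadjusted p under 0.05), PRL, which was 9.66-fold higher in 3 of 3 letters (3.27 ± 0.24, adjusted p = 0.0314, against 1 without the letter). That call was lost on leaving out any 1 of the 6 arrays (0.0979 to 0.295) and with quantile normalization (0.0748). IGFBP2, which binds insulin-like growth factors, stood at 2.30 ± 0.26 (blocked adjusted p = 0.0641, 0.0450 with the mean of probe sets and 0.0272 with a trended robust variance). SLC7A11 passed with quantile normalization (0.0329).

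Decidualization markers (median 0.21, camera adjusted p = 0.00463) and progestin and glucocorticoid responsive genes (0.21, 0.0224) were again higher as groups, with 0 of 29 members of each passing over all genes and 2 and 1 higher adjusted over the list alone (blocked, PRL passed over all genes, and 5 decidualization markers were higher over the list alone). Smooth muscle and pericyte markers moved with them (median 0.36, camera adjusted p = 0.00463; 0 of 15 passed, 1 higher adjusted over the list alone, 6 when blocked). Interferon-stimulated genes (median -0.46, camera adjusted p = 9.02e-08; 0 of 28 passed) and cytokines (-0.24, 0.0227; 0 of 21 passed) were lower, with 0 in either list adjusted over the list alone. None of the 5 held with an estimated correlation (adjusted p = 0.296, 0.296, 0.329, 0.329 and 0.296), and metalloproteinases passed camera only when blocked (0.00736, against 0.0802, but adjusted p = 0.412 with an estimated correlation). Left out singly, estradiol plus IL-1β A ended the call of the progestin list (0.199) and estradiol plus IL-1β C that of cytokines (0.294; median -0.09). Leaving out estradiol plus MPA plus IL-1β A ended those of the progestin (0.0792), decidualization (0.0747; median 0.10) and smooth muscle lists (0.0747; median 0.21). In the same group B ended those of cytokines (0.126), interferon-stimulated genes (0.30; median -0.04) and smooth muscle markers (0.0923), and C those of cytokines and the progestin list (0.0618 each). By letter the median of the interferon-stimulated genes was 0.09 in A, -1.63 in B and -0.22 in C. Without estradiol plus IL-1β A 1 gene passed.

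Both MPA effects had a Pearson correlation of 0.632 and a Spearman correlation of 0.474 across the 19732 genes. Averaged over IL-1β, 5 genes passed (limma). IMPA2 (4.79-fold, 2.26 ± 0.20, adjusted p = 0.0205), LINC01088 (5.35-fold, 2.42 ± 0.26, 0.0286; 0.10 and 0.01 on its other probe sets), FKBP5 (5.26-fold, 2.39 ± 0.28, 0.0376) and CILP (1.54-fold, 0.62 ± 0.06, 0.0286) rose, and SLC7A11 fell by 1.30 ± 0.14 (0.0286). Each of these calls was lost on leaving out most single arrays (12 of 12 for FKBP5, with adjusted p up to 0.184, and 9 of 12 for IMPA2, up to 0.127; 10 for LINC01088, up to 0.146, 10 for CILP, up to 0.145, and 11 for SLC7A11, up to 0.145). With every probe set tested, the others of FKBP5 stood at 2.34 and 2.56 and passed (limma adjusted p = 0.00814 and 0.0189). Those of SLC7A11 stood at -1.62 and -1.77 and did not pass. Quantile normalization ended the call of FKBP5 (0.0898) and the mean of probe sets that of SLC7A11 (0.458, and 0.444 over its probe sets of median 1). The count was 0 without any 1 of 7 arrays, 1 without estradiol plus MPA B, estradiol plus IL-1β A or estradiol plus MPA plus IL-1β B, 3 without estradiol C and 12 without estradiol plus MPA C.

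In the blocked fit the average MPA effect passed for 131 genes, 98 higher and 33 lower. PRL rose 8.42-fold (3.07 ± 0.17, adjusted p = 0.00391, against 0.222), IGFBP2 4.74-fold (2.24 ± 0.18, 0.00866) and CRYAB, a small heat shock protein, 2.26-fold (1.17 ± 0.10, 0.00875), while the 5 genes that passed without the letter passed here as well (0.00866 to 0.0102). OLFML1 fell by 2.59 ± 0.19 (0.00861), MMP1 by 2.27 ± 0.21 (0.00935) and NEFM, a neurofilament subunit, by 2.09 ± 0.20 (0.00946; 0.01 on its second probe set). These 6 genes, FKBP5, IMPA2 and LINC01088 each passed without any 1 array. They moved one way in 6 of 6 same-letter pairs, which the rule for naming the largest blocked changes itself requires. Without 1 of the 12 arrays the blocked count ranged from 22 without estradiol plus MPA plus IL-1β A to 205 without estradiol plus MPA C.

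Whether MPA changed the response to IL-1β was tested as the interaction, and 0 genes passed by limma in either fit (195 at an unadjusted p under 0.05, 488 when blocked). PTGS2 had an interaction of -1.67 ± 0.36, TNFAIP3 -1.21 ± 0.27 and ICAM1 -0.55 ± 0.40, while CXCL8, whose value is affected by the floor, had -2.04 ± 0.50. ACACA, acetyl-CoA carboxylase (-0.83 ± 0.16), ATPAF1 (0.68 ± 0.14), RSBN1L (-0.70 ± 0.14) and CCDC88A (-0.79 ± 0.17) had the smallest p values beside PTGS2, all with an adjusted p of 1. The other probe set of ACACA stood at 0.21, that of ATPAF1 at 0.08, that of CXCL8 at -0.91, that of PTGS2 at -1.28, that of TNFAIP3 at -1.40 and those of ICAM1 at -1.31 and -1.19. The 3 others of RSBN1L stood between -0.14 and 0.07 and the 5 others of CCDC88A between -0.57 and 0.14. As groups, NF-kB genes (median -0.23, camera adjusted p = 0.000779), adhesion genes (-0.17, 0.0422) and progestin and glucocorticoid responsive genes (-0.13, 0.0481) had lower interactions than other genes, and cell cycle genes higher ones (0.31, 3.84e-05). No member passed over all genes (0 of 21, 20, 29 and 22), 1 NF-kB gene was lower adjusted over the list alone (0 when blocked), and the other lists had 0. With an estimated correlation the adjusted p values were 0.363, 0.425, 0.425 and 0.425. Blocked, oxidative stress genes (median -0.26) and immediate early genes (-0.16) passed as well (camera adjusted p = 0.0189 each, against 0.0736 and 0.0618, but adjusted p = 0.422 each with an estimated correlation). The NF-kB call was lost without estradiol plus IL-1β C (0.0505), and the cell cycle call without estradiol B (0.0914; median 0.14). The adhesion call was lost without estradiol A, estradiol plus MPA C, estradiol plus IL-1β B or C, or estradiol plus MPA plus IL-1β B or C. The progestin call was lost without estradiol A or B, estradiol plus MPA B, estradiol plus IL-1β A, B or C, or estradiol plus MPA plus IL-1β B (both calls up to 0.499). Without estradiol plus MPA plus IL-1β B the medians of these 2 lists were -0.07 and -0.03.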

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

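Of the tests in this part, those of the raised and lowered genes with an estimated correlation and with fry, and the final reading of the smooth muscle test, were chosen after the result was seen. The patterns themselves were noticed in these data, so every explanation is a hypothesis.

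In 4 gene lists the interactions of the members differed from those of other genes by the camera test. This does not test whether the response of the list itself changed with MPA. With an estimated correlation none of the 4 passed (adjusted p = 0.363 for NF-kB genes and 0.425 for the others). Fry, which tests the members against no change, passed 0 lists for the interaction in either fit. The median interaction was -0.23 for 21 NF-kB subunits and feedback inhibitors (adjusted p = 0.000779), -0.17 for 20 genes of leukocyte adhesion and antigen presentation (0.0422), -0.13 for 29 progestin and glucocorticoid responsive genes (0.0481) and 0.31 for 22 cell cycle genes (3.84e-05). The cell cycle median was -0.29 with IL-1β under estradiol and -0.05 under estradiol plus MPA, where the mean was 0.00 and the camera direction down (adjusted p = 0.700). In single genes 0 passed the interaction by limma (195 at an unadjusted p under 0.05, and 0 and 488 blocked). The NF-kB call was lost without estradiol plus IL-1β C (0.0505), the cell cycle call without estradiol B (0.0914), and the adhesion and progestin calls without any 1 of the 6 and of the 7 arrays named in the report (up to 0.499, without estradiol plus MPA plus IL-1β B).

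Data outside the tests of genes also responded. Among 13522 probe sets, 11721 without a gene symbol and 1801 with several, 54 passed for IL-1β under estradiol (29 higher, 25 lower; 120 blocked) and 36 under estradiol plus MPA (17 higher, 19 lower; 61 blocked). Averaged over MPA 106 passed (260 blocked). For MPA 1 passed without IL-1β in either fit, 1 on average (5 blocked) and, by limma, 0 with IL-1β and for the interaction in either fit.

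The 437 genes raised by IL-1β on average rose less in the presence of MPA, with a median effect of 1.56 without MPA and 1.38 with it, and a median interaction of -0.16 ± 0.06 (jackknife over letters; -0.09 without estradiol plus MPA plus IL-1β B). A shift of whole arrays by a constant was argued against, since the 322 genes lowered on average had a median interaction of 0.11 ± 0.03, opposite to that of the raised genes. The median effect of these lowered genes was -0.95 without MPA and -0.83 with it, so both sets changed less with MPA. The signs therefore do not address a difference in scale between arrays, which was not tested. Values held at the floor of the table were too few to set this median. The 429 raised genes without a floored value on any of their probe sets had a median of -0.16. Of the 437 genes 70.3% had an interaction below 0. Leaving out the floored genes could therefore not have brought the median to 0, and this was no test. MPA may have dampened the response, for which a median below 0 was required in every letter, and it was below 0 in 3 of 3 (-0.21 in A, -0.21 in B and -0.03 in C). This stays a hypothesis, with p = 0.0168 for the raised and 0.00557 for the lowered genes in camera with an estimated correlation, against 0.0563 and 0.0442 in fry; blocked, these were 0.0175, 0.0188, 0.0344 and 0.0589.

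Smooth muscle and pericyte markers were higher with MPA, with a median average effect of 0.35 (camera adjusted p = 0.00109, and adjusted p = 0.308 with an estimated correlation; 0 of 15 passed over all genes by limma, 2 adjusted over the list alone; blocked MCAM passed at 1.07 with adjusted p = 0.0200, 11 over the list alone; ACTA2 at 0.28, TAGLN at 0.35). More smooth muscle cells or pericytes in the cultures with MPA could account for it if the members rose alike, and 4 members lay over 3 blocked standard errors from their common effect (SMTN at 0.01, LMOD1 at 0.54, ACTG2 at 0.87 and MCAM). That bound was wrong, because values relative to a median give no baseline, and a marker that decidual cells express themselves rises less for the same share of added cells. This reading was adopted after the value was seen, so added cells and a response of the decidual cells cannot be told apart, and 2 of the 15 markers stand on another list too. That 1 letter decides was argued against, as the median was 0.38 or higher with any letter left out. Levels of these markers did differ between letters, which took a median share of 0.801 of their variance within groups, against 0.456 over all genes. RGS5, also on this list, stood lower with MPA on average, at -0.36 ± 0.45 (blocked).

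Interferon-stimulated genes rose with IL-1β as a group, with a median average effect of 1.31 and 8 of 28 passing (18 adjusted over the list alone; camera adjusted p = 1.60e-15, and adjusted p = 0.126 with an estimated correlation), but 2 passed in each comparison alone; blocked, 16 passed on average and 5 and 3 without and with MPA. Differences between letters could widen their spread, and the letter took a median share of 0.334 ± 0.0527 (bootstrap SE) of their variance within groups, against 0.25 by chance and 0.456 over all genes. This share lay below that of all genes, and it was under the bound of 0.35 set beforehand by less than its error. That error resamples genes, which are not independent replicates. The share counts only a shift of a letter common to the 4 groups, so letters that respond differently to IL-1β or MPA do not enter it. The explanation thus cannot be told apart from spread of another kind. That 1 letter decides the rise was argued against, since the lowest median with a letter left out was 0.90 (without A). By letter the median IL-1β effect was 1.77, 0.89 and 1.38 under estradiol and 2.16, 0.28 and 1.04 under estradiol plus MPA, and no biological explanation was tested.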

How the results depend on the processing

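Alternatives chosen after the data were seen were centring on the probe sets of median 1, the mean of a gene's probe sets of median 1, and the blocked fit joined with another choice, with the second PGR probe set or with an estimated correlation or fry; the others were planned. Over the genes and lists named, 2056 values under an alternative kept their direction and side of the threshold, 193 no longer passed, 27 came to pass and 2 reversed. Over the counts, PGR values and correlations, 315 stayed close, 7 came to pass, 3 reversed and the others moved. Of 84 values that other probe sets gave for 28 genes named without the block, counted once per comparison, 77 had the same sign, 51 lay within a log2 of 1 of the value printed and 0 passed in the opposite direction. Where fewer arrays or genes entered a fit, that explains part of the change; for the rest the cause was not tested. The table keeps no brightness, so what signal over background limited could not be read.

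The blocked fit raised the counts of the IL-1β effect from 299 to 931 under estradiol, from 199 to 562 under estradiol plus MPA and from 759 to 1920 on average, those of MPA with IL-1β from 0 to 1 and the average MPA effect from 5 to 131. The calls of PGR, of genes named and of lists that it changed stand beside the results. Array weights gave 556 genes for IL-1β under estradiol, 318 under estradiol plus MPA, 1269 for its average and 9 for the average MPA effect. Without the genes of lowest mean these were 152, 63, within 1.5 times and 1. Every probe set on its own gave 464 genes for IL-1β under estradiol, 2 for MPA without IL-1β, 1 with it and 10 on average. The mean of probe sets gave 1 for MPA with IL-1β and 11 on average (12 over probe sets of median 1). With only the groups compared, 189 and 64 genes passed for IL-1β without and with MPA. A trended robust variance gave 1 gene for MPA without IL-1β, quantile normalization 1 with it, and a 2-fold minimum 432 for the average IL-1β effect.

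Joined with the block, MPA without IL-1β had 1 gene with quantile normalization, 20 with arrays centred on their medians, 23 with the mean of probe sets, 11 with every probe set, 19 without the genes of lowest mean and 18 with a trended robust variance, against 0 (limma, 1935 at an unadjusted p under 0.05). MPA with IL-1β had 3 with centring, 13 with the mean, 6 with every probe set, 10 without the genes of lowest mean and 11 with the trended variance, against 1. The second PGR probe set passed with the block, at -1.93 and -1.80 for IL-1β without and with MPA and -2.22 and -2.09 for MPA without and with IL-1β. The mean of both probe sets passed with the block at -1.83 and -1.55 for IL-1β without and with MPA and at -1.84 (adjusted p = 0.0497) for MPA without IL-1β.

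The numbers of lists past the camera test were 9 for IL-1β under estradiol, 8 under estradiol plus MPA, 6 and 5 for MPA without and with IL-1β, and 4 for the interaction. With an estimated correlation they were 5, 5, 1, 0 and 0, and joined with the block 5, 4, 0, 0 and 0. In camera with an estimated correlation 3 lists had an unadjusted p under 0.05 both for MPA with IL-1β and for the interaction. Joined with the block these were 4, 3 and 1 for MPA without IL-1β, with it and the interaction. With fry 1 list passed for MPA without IL-1β, 0 with it and 0 for the interaction (4, 3 and 0 at an unadjusted p under 0.05), and joined with the block 4, 2 and 0 (the last with 0 at an unadjusted p under 0.05). In camera at its preset correlation, quantile normalization left 2 lists for the interaction, against 4. The correlation of the IL-1β effects was 0.884 with quantile normalization, 0.926 with the mean of probe sets, 0.923 over probe sets of median 1, 0.859 without the genes of lowest mean and 0.821 with array weights, and that of the MPA effects 0.435 with array weights.

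With 1 array left out, counts ranged from 166 to 263 for IL-1β under estradiol (428 to 618 blocked), 101 to 190 under estradiol plus MPA (228 to 443), 521 to 827 on average (1231 to 1954), 0 to 6 for MPA without IL-1β (0 to 17), 0 to 1 with it (0 blocked in each case), 0 to 12 on average (22 to 205) and 0 for the interaction in both fits. Moves of more than 1.5 times came, for IL-1β under estradiol, without estradiol B (166) and estradiol plus IL-1β C (176), and under estradiol plus MPA without estradiol plus MPA B (128), estradiol plus MPA plus IL-1β A (101) and estradiol plus MPA plus IL-1β C (132). For MPA without IL-1β they came without estradiol C (4), estradiol plus MPA B (1) and estradiol plus MPA C (6), and with IL-1β without estradiol plus IL-1β A (1). The average MPA effect had 12 genes without estradiol plus MPA C, 3 without estradiol C and 0 or 1 without any other array. Blocked, the first 2 counts fell without each of their arrays, but for estradiol plus MPA A in the second (443), the average of IL-1β without estradiol plus MPA plus IL-1β A (1231), and that of MPA without each array except estradiol plus MPA C, without which it was 205. Lists past the camera test ranged from 8 to 11, 6 to 10, 4 to 8, 3 to 5 and 1 to 7, in that order; MPA with IL-1β had 3 without estradiol plus MPA plus IL-1β A, and the interaction 1 without estradiol plus IL-1β C, 2 without estradiol A or estradiol plus MPA plus IL-1β B and 7 without estradiol plus MPA plus IL-1β A. Correlations were 0.829 to 0.873 for IL-1β and 0.407, without estradiol plus MPA A, to 0.634 for MPA. First-probe-set values of PGR lay between -2.42 and -1.19 for IL-1β under estradiol, -1.96 and -0.57 under estradiol plus MPA, -2.19 and -0.80 for MPA without IL-1β and -1.55 and -0.71 with it. The PGR interaction lay between -0.24 and 1.16 and reversed without estradiol A (-0.11), estradiol plus MPA C (-0.24) and estradiol plus IL-1β C (-0.09). The median of the oxidative stress list under estradiol plus MPA lay between -0.039 and 0.497 and reversed without estradiol plus MPA B (-0.039) and without estradiol plus MPA plus IL-1β C (-0.028). The fit on only the groups compared was not run for the interaction and the averages, which use every group, and an added constant was not applied, since the deposited values were log2 already.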

Other observations

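The tests of other groupings of the arrays were chosen after the counts were seen. Beyond the lists led by chemokines, IL-1β under estradiol raised single members of several lists; in each gene past the threshold without the letter, the arrays of the groups compared did not overlap. IRAK2, a kinase that relays the signal of the IL-1 receptor, rose 3.77-fold (1.91 ± 0.27, limma adjusted p = 0.00884; 4.50, past the threshold, and 0.02 on its other probe sets), alone among 20 genes of the IL-1 and Toll-like receptor pathway (1 higher adjusted over the list alone; blocked 2 higher, and 2 higher and 1 lower over the list alone; median 0.11; camera adjusted p = 0.0614). PLAUR, the urokinase receptor, rose 3.77-fold (1.91 ± 0.26, 0.00606; 1.90, past the threshold, and 0.61 on its other probe sets), while 14 other genes of haemostasis and fibrinolysis did not pass (1 higher and 1 lower adjusted over the list alone; blocked 1 lower as well, and 3 higher and 1 lower over the list alone; median 0.02; camera adjusted p = 0.578). MYB, a transcription factor on the oestrogen responsive list, rose 11.4-fold (3.51 ± 0.37, 0.00148; 0.08 on its other probe set) and 12.1-fold with MPA present (3.60 ± 0.37, 0.00160; 0.0774 with only the groups compared), while 17 of 18 members did not pass in either (under estradiol 4 were lower over the list alone when blocked; medians -0.07 and -0.14; camera adjusted p = 0.578 and 0.845, the second with a mean of 0.03 and an upward test). In the list of uterine activation and contraction PTGS2 rose and 15 of 16 did not pass (1 lower over the list alone when blocked; median 0.03; camera adjusted p = 0.578). SERTAD4, named among the largest changes, fell by 2.82 ± 0.40 (0.00844; 0.0542 with only the groups compared; its 3 other probe sets stood between -2.31, which passed, and -0.24). KLF4, a transcription factor on the progestin list, fell by 1.84 ± 0.18 under estradiol and by 1.79 ± 0.18 with MPA present in the blocked fit alone (0.00180 and 0.00269, against 0.390 and 0.519).

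KDR, the main receptor of VEGF, fell by 0.88 ± 0.13 with IL-1β under estradiol (adjusted p = 0.0105; 0.0511 without estradiol plus IL-1β C and 0.0516 with only the groups compared). It was the only member past the threshold of 19 angiogenic factors (3 higher and 1 lower adjusted over the list alone; 4 higher and 1 lower blocked, and 6 and 2 over the list alone; median 0.17; camera adjusted p = 0.0614, and 0.0203 blocked, but adjusted p = 0.130 with an estimated correlation in that fit) and of 15 endothelial markers (median 0.03; 0.753). With MPA present the angiogenic list passed camera (median 0.16; 0.0107; adjusted p = 0.146 with an estimated correlation) with 0 of 19 members past the threshold by limma and 3 higher adjusted over the list alone (2 and 5 blocked), and its call was lost without estradiol plus MPA A (0.148) or estradiol plus MPA plus IL-1β B (0.164). Trophoblast markers passed under estradiol at a median of 0.03 (0 of 18 members, 1 adjusted over the list alone and 0 when blocked; camera adjusted p = 0.0412, 0.0552 blocked, and adjusted p = 0.259 with an estimated correlation), and this was lost without estradiol A (0.0784), estradiol B (0.0550) or estradiol plus IL-1β A (0.0642; median 0.01). LMOD1 was the only one of 15 smooth muscle and pericyte markers to pass under estradiol, where it fell by 0.69 ± 0.13 (0.0387; -1.25 on its other probe set, which passed at 0.0249), but without any 1 of the 6 arrays it did not pass (0.0631 to 0.149), nor with arrays centred on their medians (0.0662), a trended robust variance (0.0620) or only the groups compared (0.134).

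No member passed over all genes by limma with IL-1β under estradiol in the remaining lists, which were not past camera either. They were collagens and other matrix proteins (24 genes, median -0.09, camera adjusted p = 0.0614), the unfolded protein response (16, -0.05, 0.568), cholesterol synthesis (14, -0.02, 0.940), leukocyte markers (20, 0.03, 0.234), epithelial markers (14, 0.01, 0.953), stromal markers (15, -0.12, 0.373) and housekeeping genes (11, -0.01, 0.953). Adjusted over the list alone, 1 gene was higher and 1 lower in the unfolded protein response and 0 in the others. Blocked, 1 gene of the unfolded protein response and 1 of cholesterol synthesis were higher and 1 stromal marker lower over all genes, and over the list alone 2 higher and 3 lower, 3 higher, and 1 lower. The mean of the unfolded protein response (0.04), of cholesterol synthesis (0.20, with an upward test), of epithelial markers (-0.09, with a downward test) and of housekeeping genes (0.00) differed in sign from the median. The smooth muscle list had a median of -0.07, a mean of 0.01 and a downward test (camera adjusted p = 0.450). Averaged over MPA, 3 lists passed camera for IL-1β only without the letter, the IL-1 and Toll-like receptor pathway, trophoblast markers (0.0373 each) and cell cycle genes (0.0210), against 0.0531 for each when blocked, and with an estimated correlation none held (adjusted p = 0.126, 0.310 and 0.404). Metalloproteinases passed only when blocked, for the average effects of IL-1β (0.0224, against 0.0603) and of MPA (0.00498, against 0.0573), as did housekeeping genes for MPA (0.0485, against 0.0617), and none held with an estimated correlation in that fit (adjusted p = 0.336, 0.310 and 0.310).

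Other groupings of the same arrays were counted for each number of genes. For 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real split gave 299 genes for IL-1β under estradiol and 199 under estradiol plus MPA, each time the only 1 of 10 to reach its count, and the highest other gave 1 in both. For MPA the real splits gave 0 (limma; 812 and 616 at an unadjusted p under 0.05) without and with IL-1β, which all 10 reached, and the highest others 3 and 15. The 4 swaps within same-letter pairs of the blocked fit are too few as well, with 931, 562, 0 and 1 in the real arrangement, reached by 1, 1, 4 and 1 of 4, and 0 as the highest other in each. For the average IL-1β effect, only the real arrangement among 100 drawn splits reached 759 (highest other 38). Blocked, only the real arrangement among 32 swaps reached 1920 (highest other 2). No share below 1 of 32 was possible for the swaps. Most drawn splits, unlike the real one, left same-letter arrays on one side. Chance is thus unlikely but not excluded. For the average MPA effect 5 of 100 drawn splits reached 5 genes, so without the letter chance cannot be excluded. Blocked, only the real arrangement among the 32 swaps reached 131 (highest other 0). This is the smallest share that 32 swaps allow, which makes chance unlikely there without excluding it. The highest other split of the MPA average gave 768 genes, many times the real count, which points to a structure of the samples: it left same-letter arrays on one side, and the 19 drawn splits that, like the real one, parted every same-letter pair gave at most 0 besides it. For IL-1β the 20 that parted every pair likewise gave at most 0 besides the real one. For the interaction all 100 drawn orders of the residuals reached 0, and the highest gave 5. Wherever the real count was 0, here and for MPA above, any grouping reaches it, so these shares decide nothing.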
